A study of Mus musculus with 24 samples.

How the data were processed

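Heart RNA of wild-type mice was isolated with TRI Reagent, selected for poly(A) mRNA and sequenced as single-end reads on an Illumina instrument, from samples with an RNA integrity number above 8, per the labels' protocols and the series' design text. The authors deposited expected counts, estimates of the number of reads per gene that need not be whole, in 1 table for each time, and per the submitters' processing notes these came from RSEM on the mouse genome GRCm38 (mm10). DESeq2 is also named there. Versions, parameters, the annotation and the strand setting are not given in the sources used here. Both tables had been filtered before deposit by a rule not given in the sources used here: the table of 16 h holds 10393 genes, that of 72 h holds 7723 genes, and 7407 are in both. A low gene that is in 1 table alone therefore says nothing about its change at the other time.

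Groups were taken from the labels, which place 24 samples in 8 groups of 3 and give 1 batch to all. At 72 h, 6 columns carry a code that no label uses and were not used here, so the hesperitin groups at that time were not analysed here. One of the 3 DOX columns at 72 h carries a number that no label has and entered as a replicate without a number. No 2 libraries agreed within sampling noise. The labels do not state how many animals stand behind each sample, so p-values measure the spread between these samples.

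Expected counts were rounded to whole numbers, scaled with TMM factors and filtered with filterByExpr, which removed no gene at 16 h and left 7703 genes at 72 h. Each comparison was tested in edgeR 4.0.16 (R 4.3.3) with a robust quasi-likelihood fit of group means, on 12 libraries at 16 h (8 residual degrees of freedom), 6 at 72 h (4) and 18 for the difference between times (12), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. CPM values are TMM-scaled within a table, and levels are not comparable between the tables. Log2 CPM used a prior count of 2. The SE beside a log2 fold change was derived as the absolute change divided by the square root of the test's F statistic. A planned fit of 12 libraries at 72 h became a fit of 6. Of 48 gene lists written down in advance, those with at least 3 tested genes were tested with camera of limma 3.58.1 (43 lists at 16 h, 41 at 72 h), at a preset correlation of 0.01 between genes. None of the calls in any of the 8 comparisons held with a correlation estimated per list, and those values stand beside each call.

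The tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined, except where a test or alternative is said to have been chosen after. The rule names, per comparison, the 8 largest rises and 8 largest falls past the threshold at a mean log2 CPM of at least 1 without overlap between the groups, up to 4 members with the smallest p for each list called or with at least 0.25 of its members past the threshold, Cisd1, Cisd2 and Cisd3, and the 4 genes with the smallest p. Unnamed gene models were left out, and the text names fewer than the rule gives. Gene positions come from the GENCODE annotation of GRCm38, matched by gene identifier, and GC content and length are those of each gene's longest annotated transcript.

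Alternatives were RLE and upper quartile factors, no filter on low counts, a mean of at least 5 CPM, DESeq2 1.42.0, limma voom, a test against a fold of 1.5 (glmTreat), a block for the label's replicate number, only the groups compared, an estimated correlation and each library left out. Voom with sample quality weights, offsets corrected for GC content and leaving out libraries of groups not compared were added after the data were seen. The tests were run on simulated counts with 200 changed genes per comparison. In DOX against V at 16 h they recovered 35.8% of 1.5-fold, 91.0% of 2-fold and 98.5% of 4-fold changes among 10393 genes, and 5.66% of calls were false. In DOXH against DOX they recovered 82.1% of 2-fold changes, in H against V 89.6%, in the interaction 49.3% and in DOX against V at 72 h 97.0% among 7703 genes. The simulation gave each gene 1 spread in all groups and the same change in all 3 libraries of a group. The real DOXH libraries lay far apart, so the shares for comparisons with DOXH and for the interaction may be too high. Depth of 9255651 to 20587578 counts per library and 3 libraries per group limit calls of changes under 1.5-fold. In all, 6 symbols at 16 h belong to more than 1 identifier and were not named.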

Results

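Hearts of wild-type mice were sequenced after a dose of doxorubicin, an anthracycline chemotherapy drug whose use is limited by injury to the heart. Some mice received hesperitin, a flavanone of citrus fruit usually spelled hesperetin, alone or with doxorubicin. The groups are vehicle (V), hesperitin at 10 mg/kg per day (H), doxorubicin at 25 mg/kg (DOX) and both compounds (DOXH), and hearts were taken 16 h or 72 h after treatment. The labels name 24 heart samples in 8 groups of 3. The 18 libraries analysed here form 6 groups of 3: all 4 groups at 16 h, and V and DOX at 72 h. At 16 h the tables held 9255651 to 11074450 counts per library in V, DOX and DOXH and 17664060 to 19869050 in H, and at 72 h they held 16607805 to 20587578. The first principal component of log2 CPM (counts scaled to library size) carried 60.8% of the variance at 16 h and 77.4% at 72 h, and it placed the 3 DOX libraries of each time apart from the 3 V libraries. The DOXH libraries did not group on it: they lay at 8.28, 35.1 and -17.7, against 29.4 to 42.2 in DOX and -20.8 to -18.0 in V.

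The series title names CISD2, so the CISD family was described first. Cisd2 encodes an iron-sulfur protein of the endoplasmic reticulum and outer mitochondrial membrane, Cisd1 (mitoNEET) a relative on the outer mitochondrial membrane, and Cisd3 a relative inside the organelle. All 3 transcripts fell with doxorubicin at both times. At 16 h Cisd2 read 68.2 ± 3.11 CPM in V and 56.8 ± 5.15 CPM in DOX (mean ± SD, n = 3), a log2 fold change of -0.26 ± 0.09 (SE; edgeR adjusted p = 0.0494). Cisd1 fell by 0.29 (adjusted p = 0.0127) and Cisd3 by 0.52 (adjusted p = 0.0135) on the log2 scale. At 72 h Cisd2 read 65.9 ± 3.71 CPM in V and 49.7 ± 5.47 CPM in DOX, a log2 fold change of -0.41 ± 0.09 (edgeR adjusted p = 0.00522), beside -0.33 for Cisd1 (adjusted p = 0.0183) and -0.65 for Cisd3 (adjusted p = 0.00136). The difference between the times was not past the threshold for Cisd2 (-0.15 ± 0.13, adjusted p = 0.408).

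With hesperitin, Cisd2 read 66.1 ± 6.99 CPM in DOXH and 76.0 ± 2.97 CPM in H at 16 h. Neither difference passed the test: DOXH exceeded DOX by 0.22 ± 0.09 on the log2 scale (adjusted p = 0.24) and H exceeded V by 0.16 ± 0.09 (adjusted p = 0.851). Without DOXH replicate 3 the first difference was 0.13 (adjusted p = 0.645), and with offsets corrected for GC content, chosen after seeing the data, the second was 0.10 (adjusted p = 1). Against V the DOXH hearts differed by -0.04 (adjusted p = 0.831), and against H by -0.20 (adjusted p = 0.203). Adjusted over the list alone, all 3 CISD genes were higher in DOXH than in DOX, but 0 passed over all genes. Adjusted over their own list, 57 of 77 nuclear oxidative phosphorylation genes were higher too, so such a shift was not particular to the CISD family. The camera list test called the family lower in DOX than V at 16 h (adjusted p = 0.0453) and higher in DOXH than DOX (adjusted p = 0.0219), but not with an estimated correlation between genes (adjusted p = 0.377 and adjusted p = 0.326 with an estimated correlation). The 16 h fall of Cisd2 lay close to the threshold: leaving out any 1 of 8 of the 12 libraries ended the call, with log2 values from -0.34 to -0.22. In the annotation of GRCm38, Cisd2 (ENSMUSG00000028165) lies on chromosome 3 from 135406412 to 135423925, Cisd1 (ENSMUSG00000037710) on chromosome 10 from 71330480 to 71344954, and Cisd3 (ENSMUSG00000078695) on chromosome 11 from 97685826 to 97688621.

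**Figure D1:**
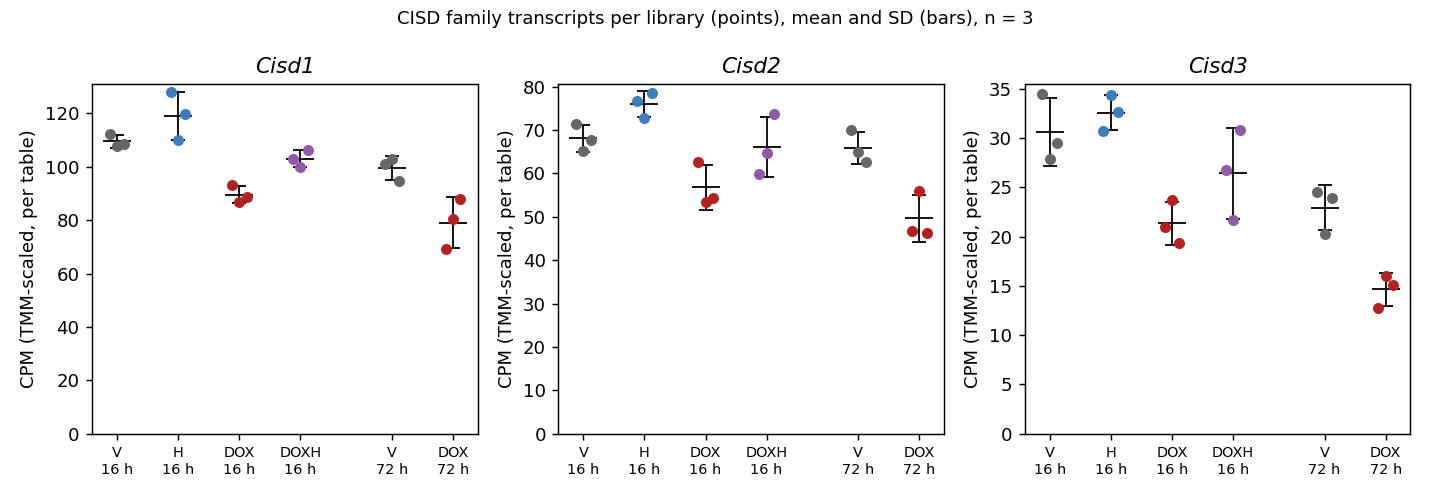
TMM-scaled CPM of Cisd1, Cisd2 and Cisd3 in each library (points) by treatment and time, with the mean and SD of each group of 3 (bars). Cisd2 averaged 68.2 CPM in V, 56.8 in DOX and 66.1 in DOXH at 16 h, and 65.9 in V and 49.7 in DOX at 72 h.

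Doxorubicin against vehicle at 16 h asks what the drug does to the heart within a day. Genes of the p53 and interferon responses rose, and genes of the contractile apparatus, calcium handling and energy metabolism fell. Of 10393 genes tested, 1624 rose and 1728 fell. The largest falls included Nppb, which encodes the cardiac stress hormone BNP (log2 fold change -6.01 ± 1.14), the clock output factor Dbp (-3.65 ± 0.65), the cardiac leucine-rich repeat protein gene Lrrc10 (-2.93 ± 0.46) and the genes of the vasoactive peptide apelin and its receptor, Apln (-2.38 ± 0.46) and Aplnr (-2.92 ± 0.57). Among the largest rises were the schlafen gene Slfn4 (4.76 ± 0.80) and Cldn5, which encodes a tight-junction protein of endothelium (2.99 ± 0.38), each at an edgeR adjusted p below that of Nppb (0.00512).

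Among p53 targets, 20 of 27 tested genes rose and none fell over all genes, with a median of 1.40 on the log2 scale. Adjusted over the list alone, 21 rose and 2 fell. Examples are Eda2r, a receptor of the tumour necrosis factor family (4.75 ± 0.85, adjusted p = 0.00425), Phlda3, an inhibitor of Akt (2.96 ± 0.58), Sesn2, a sestrin (2.89 ± 0.54), and Cdkn1a, the cell cycle inhibitor p21 (2.88 ± 0.75, adjusted p = 0.0164). Of 24 interferon-stimulated genes, 23 rose both over all genes and adjusted over the list alone (median 1.63), and those with the smallest p include Parp14 (1.52 ± 0.20), Rtp4 (1.81 ± 0.25) and Herc6 (1.67 ± 0.26). Both lists were called by camera (adjusted p = 2.57e-07 and adjusted p = 2.05e-12), with adjusted p = 0.377 and adjusted p = 0.361 with an estimated correlation. Immediate early genes went the same way: 9 of 18 rose, 11 adjusted over the list alone, among them Fos (2.76 ± 0.45) and Fosl2 (2.09 ± 0.35), at adjusted p = 0.000203 and adjusted p = 0.413 with an estimated correlation.

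The muscle cell's own genes fell as a body. Of 25 sarcomere genes 24 fell (median -0.74), adjusted over the list alone too, including cardiac actin Actc1 (-1.42 ± 0.19), the ventricular light chain Myl2 (-0.56 ± 0.07) and troponin C, Tnnc1 (-0.67 ± 0.09). All 15 cardiomyocyte markers fell (median -0.65), 15 adjusted over the list alone. Of 23 calcium-handling genes 15 fell, 16 adjusted over the list alone, among them the channel subunit gene Cacnb2 (-1.98 ± 0.25), phospholamban (Pln, -0.96 ± 0.16) and calsequestrin (Casq2, -1.04 ± 0.15). These 3 lists were called (adjusted p = 7.63e-13, adjusted p = 1.18e-09 and adjusted p = 3.61e-07), each at adjusted p = 0.361 with an estimated correlation. Of 20 cardiac ion channel genes 7 fell and 1 rose, 9 and 1 adjusted over the list alone, and the potassium channel gene Kcnq1 (-1.98 ± 0.40) is among those that fell (camera adjusted p = 0.00852, adjusted p = 0.546 with an estimated correlation).

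Energy metabolism moved by smaller steps. Of 77 nuclear-encoded genes of oxidative phosphorylation 42 fell, 46 adjusted over the list alone, and none rose (median -0.21), among them the complex I genes Ndufb10 (-0.70 ± 0.10) and Ndufa8 (-0.56 ± 0.07). In the list of the tricarboxylic acid cycle 12 of 22 fell, 17 adjusted over the list alone, with Idh3a, a subunit of mitochondrial isocitrate dehydrogenase (-0.56 ± 0.10), and the cytosolic malate dehydrogenase gene Mdh1 (-0.57 ± 0.08). Glycolysis lost 17 of 22 genes and gained 1, 19 and 1 adjusted over the list alone, including the insulin-responsive glucose carrier Slc2a4 (-1.87 ± 0.32) and muscle phosphoglycerate mutase, Pgam2 (-1.07 ± 0.14). These 3 lists were called (adjusted p = 8.15e-14, adjusted p = 8.94e-08 and adjusted p = 1.27e-07), again each at adjusted p = 0.361 with an estimated correlation. Cytosolic ribosomal protein genes did not move: 0 of 38 passed edgeR's test, and 0 adjusted over the list alone, at a median of -0.01.

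Clock genes went both ways: of 17, 10 fell and 2 rose, 11 and 3 adjusted over the list alone (camera adjusted p = 0.0149, adjusted p = 0.361 with an estimated correlation). The repressors Ciart (-2.84 ± 0.30) and Per2 (-1.23 ± 0.15) fell, and Arntl, which encodes the activator BMAL1, rose (2.05 ± 0.28). Markers of other cells moved as well. Of 14 macrophage and monocyte markers 3 rose and 1 fell, also adjusted over the list alone, with Mrc1 (0.88 ± 0.12) and F13a1 (0.79 ± 0.10) among the rises, and of 9 neutrophil markers 2 rose, 6 adjusted over the list alone (median 2.30). Camera called both (adjusted p = 0.0211 and adjusted p = 0.00218), each at adjusted p = 0.546 with an estimated correlation. Mural cell markers went the other way, with 5 of 13 lower, also adjusted over the list alone (median -0.34). Camera called them at adjusted p = 0.0472, with adjusted p = 0.546 with an estimated correlation. The acute-phase gene Serpina3n rose by 3.13 ± 0.97 (adjusted p = 0.0331), but 1.73 without DOX replicate 1 (adjusted p = 0.161), and without any 1 of the 3 V libraries its call also ended. Without V replicate 1 the count of changed genes was 1928, without V replicate 3 it was 2021 and without DOX replicate 1 it was 2230. Against a fold of 1.5 (glmTreat), 91 genes passed, all of them among the 3352.

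At 72 h the same comparison shows the hearts 3 days after the drug. Transcripts of the myosin heavy chains moved in opposite directions. Myh7, the slow form of the fetal and stressed rodent heart, rose by 5.73 ± 0.15 on the log2 scale. It went from 66.7 ± 10.4 to 3541 ± 259 CPM (SD, n = 3). The adult form Myh6 changed by -2.66 ± 0.18, and myosin protein was not measured here. Acute-phase and inflammatory genes rose, cytosolic ribosomal protein genes rose almost without exception, many mitochondrial and ion channel genes fell, and globin transcripts nearly vanished. Of 7703 genes tested, 2038 rose and 2095 fell (edgeR, adjusted p under 0.05), and 826 passed against a fold of 1.5, all of them among the 4133. On chromosome 14 the neighbours Myh6 (54941921 to 54966927) and Myh7 (54970684 to 54994626) share much of their coding sequence, so reads can be split between them by the counting. Their opposite directions do not settle this, because a shift of shared reads would also give them, and their summed counts were not tested here.

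Of 17 tested genes of inflammation and the acute phase, 13 rose over all genes and adjusted over the list alone, and none fell (median 2.19). Serpina3n rose by 5.12 ± 0.42, the protease inhibitor gene Timp1 by 5.08 ± 0.57, the siderophore-binding lipocalin Lcn2 by 5.62 ± 0.80 and the oncostatin M receptor gene Osmr by 2.01 ± 0.21. The 3 tested neutrophil markers rose, also adjusted over the list alone: S100a8 (6.27 ± 0.97), S100a9 (5.73 ± 0.96) and Retnlg (6.29 ± 0.81). Their list was not called by camera (adjusted p = 0.464). Among macrophage and monocyte markers 9 of 12 rose and 1 fell, 10 and 1 adjusted over the list alone, with Lyve1 (1.31 ± 0.13) and F13a1 (1.16 ± 0.14) as examples. Chil3, a chitinase-like protein gene of myeloid cells, rose by 7.31 ± 0.73, while the MHC class II gene H2-Aa changed by -2.65 ± 0.13. The inflammatory and macrophage lists were called (adjusted p = 0.00108 and adjusted p = 0.0042), both at adjusted p = 0.454 with an estimated correlation.

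Ribosomal protein genes rose in 37 of 38 cases, in 38 adjusted over the list alone (median 0.65, camera adjusted p = 1.81e-12, adjusted p = 0.452 with an estimated correlation). Rpl3 rose by 1.26 ± 0.11, Rps19 by 1.03 ± 0.11 and Rpl10a by 0.92 ± 0.09. Genes of the fasting and glucocorticoid response rose in 14 of 20 cases and fell in 1, also adjusted over the list alone (median 1.40, adjusted p = 0.00228, adjusted p = 0.452 with an estimated correlation). They include Pdk4, the kinase that restrains pyruvate oxidation (3.34 ± 0.34). Among p53 targets 10 of 19 rose and 2 fell, the same counts adjusted over the list alone. Cdkn1a (3.63 ± 0.20) and the cell death gene Bax (1.11 ± 0.09) rose, and the cyclin gene Ccng1, itself induced by p53, changed by -1.45 ± 0.08 (list adjusted p = 0.0474, adjusted p = 0.424 with an estimated correlation).

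Mitochondrial transcripts fell on both genomes. Of 13 mRNAs encoded in the mitochondrial genome 12 fell, 13 adjusted over the list alone (median -0.81), such as mt-Nd1 (-0.87 ± 0.09) and mt-Nd2 (-1.01 ± 0.10). Their share of all counts was 34.8 ± 0.937% in V and 27.3 ± 1.47% in DOX, and nuclear copies of mitochondrial sequence took a further 12.1% to 15.5% per library at this time. Of 22 tricarboxylic acid cycle genes 19 fell, also adjusted over the list alone, with citrate synthase, Cs, at -1.15 ± 0.10. For oxidative phosphorylation 42 of 77 nuclear genes fell, with 42 lower and 1 higher adjusted over the list alone, for example Uqcrc1 of complex III (-0.96 ± 0.08). Of 22 glycolysis genes 16 fell and 2 rose, 18 and 2 adjusted over the list alone, with hexokinase Hk2 (-2.29 ± 0.16) and the muscle enolase Eno3 (-1.68 ± 0.13). The mitochondrial mRNA, cycle and glycolysis lists were called (adjusted p = 1.45e-05, adjusted p = 3.99e-07 and adjusted p = 3.26e-05), each at adjusted p = 0.424 with an estimated correlation. The oxidative phosphorylation list was called at adjusted p = 8.43e-07, with adjusted p = 0.474 with an estimated correlation.

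Ion channel genes, calcium-handling genes and cardiomyocyte markers mostly fell. Of 25 sarcomere genes 15 fell, 1 rose and 9 did not pass, with 16 lower and 1 higher adjusted over the list alone (median -0.42, adjusted p = 0.000691, adjusted p = 0.452 with an estimated correlation). Of 16 cardiac ion channel genes 14 fell, also adjusted over the list alone (median -0.92), including the pacemaker channel Hcn2 (-2.63 ± 0.22) and the potassium channel Kcnd2 (-1.93 ± 0.17). Of 23 calcium-handling genes 13 fell and 2 rose, again the same adjusted over the list alone, with the ryanodine receptor Ryr2 (-1.74 ± 0.12) and the calcium pump Atp2a2 (-1.34 ± 0.12). Of 15 cardiomyocyte markers 12 fell, 13 adjusted over the list alone (median -1.08), for example troponin I, Tnni3 (-1.09 ± 0.12). Camera called the ion channel, calcium and cardiomyocyte lists (adjusted p = 5.91e-05, adjusted p = 0.00297 and adjusted p = 2.38e-05), at adjusted p = 0.424 with an estimated correlation. In contrast 13 of 21 endothelial markers rose and 1 fell, 14 and 1 adjusted over the list alone (median 0.42, adjusted p = 0.00297, adjusted p = 0.424 with an estimated correlation).

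Of 9 erythroid markers 7 fell, also adjusted over the list alone (median -5.92, adjusted p = 0.00297, adjusted p = 0.452 with an estimated correlation). The beta-globin gene Hbb-bs, on chromosome 7 from 103826534 to 103828096, went from 1029 ± 409 to 11.4 ± 2.79 CPM (SD, n = 3; log2 fold change -6.50 ± 0.43). Hba-a1 changed by -5.92 ± 0.59, Hba-a2 by -6.56 ± 0.43, Hbb-bt by -8.26 ± 0.50, and Alas2, the haem synthesis enzyme of red cell precursors, by -6.56 ± 0.57. The paired globin genes are near-identical, so how reads were split within each pair is uncertain. The count of changed genes at this time ranged from 3397 to 4022 with 1 library left out.

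**Figure D2:**
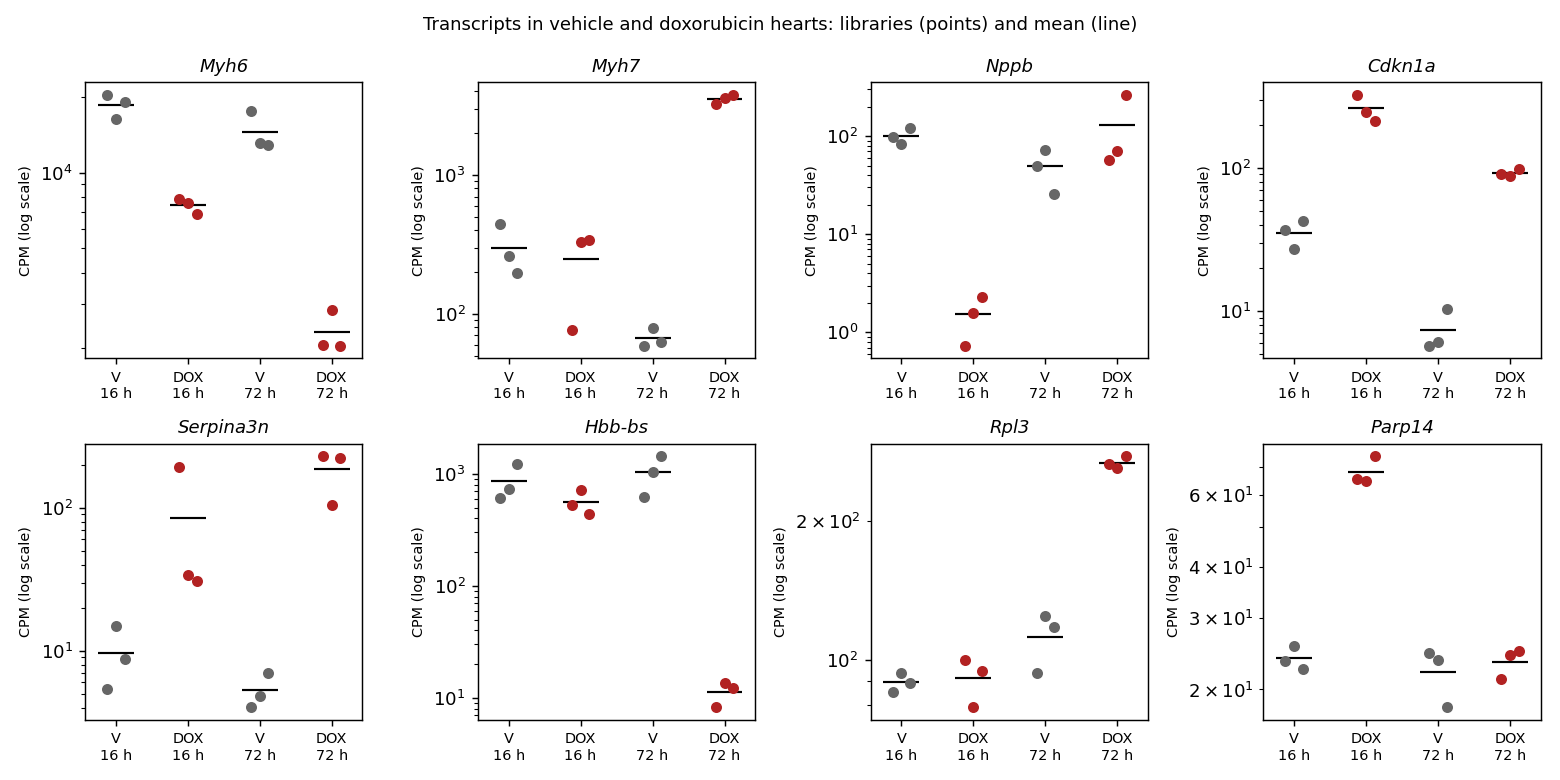
CPM on a log axis of 8 genes in each V and DOX library at 16 h and 72 h (points), with group means of 3 (lines). Myh7 in DOX lies near 3541 CPM at 72 h against 66.7 in V, and Hbb-bs lies near 11.4 against 1029.

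The difference between the times was itself tested in the 7407 genes present in both tables, by setting the doxorubicin change at 72 h against that at 16 h. It was past the threshold for 1960 genes, with 935 higher and 1025 lower at 72 h (edgeR), and for 108 against a fold of 1.5, all among the 1960. With a block for the replicate number the count was 1214 (1163 shared) and the lists called went from 10 to 5. Which lists were lost with the block was not recorded, so the list calls given for this difference are those of the fit without it. Of 15 cardiac stress genes 7 were higher at 72 h and 8 did not pass, with 7 higher adjusted over the list alone (adjusted p = 0.0287, adjusted p = 0.822 with an estimated correlation). Nppb differed by 7.41 ± 1.46, Myh7 by 5.99 ± 1.28 and the ankyrin repeat gene Ankrd1 by 4.09 ± 0.89. Nppb had been among the largest falls at 16 h, so much of its difference is the loss of that fall. Interferon-stimulated genes went back, with 10 of 13 lower at 72 h (11 adjusted over the list alone), such as Parp14 (-1.44 ± 0.26) and Gbp3 (-2.14 ± 0.43). Ribosomal protein genes were higher in 37 of 38 cases (38 adjusted over the list alone), such as Rpl3 (1.22 ± 0.18), and erythroid genes lower in 6 of 9 (8 adjusted over the list alone), such as Hbb-bs (-5.89 ± 0.46).

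The interferon, ribosomal and erythroid lists were called (adjusted p = 0.000187, adjusted p = 4.49e-19 and adjusted p = 4.16e-06), at adjusted p = 0.809, adjusted p = 0.809 and adjusted p = 0.549 with an estimated correlation. Many genes changed alike at both times. Of 7405 genes tested in both, 479 rose at both (286 would do so if the lists were independent) and 933 fell at both (406 if independent), while 81 rose and then fell (296 if independent) and 88 fell and then rose (392 if independent). The correlation of the changes across genes was 0.521, and genes are not independent replicates. Each time has its own vehicle libraries and its own table, and differences between the tables in library preparation or counting enter this comparison. Nuclear copies of mitochondrial sequence took 12.1% to 15.5% of counts per library at 72 h and 0% at 16 h. The share of 18S rRNA ran from 0.540% to 1.63% at 72 h and from 0.0327% to 0.0874% at 16 h. Time differences of mitochondrial mRNAs may therefore come in part from how mitochondrial reads were counted.

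**Figure D3:**
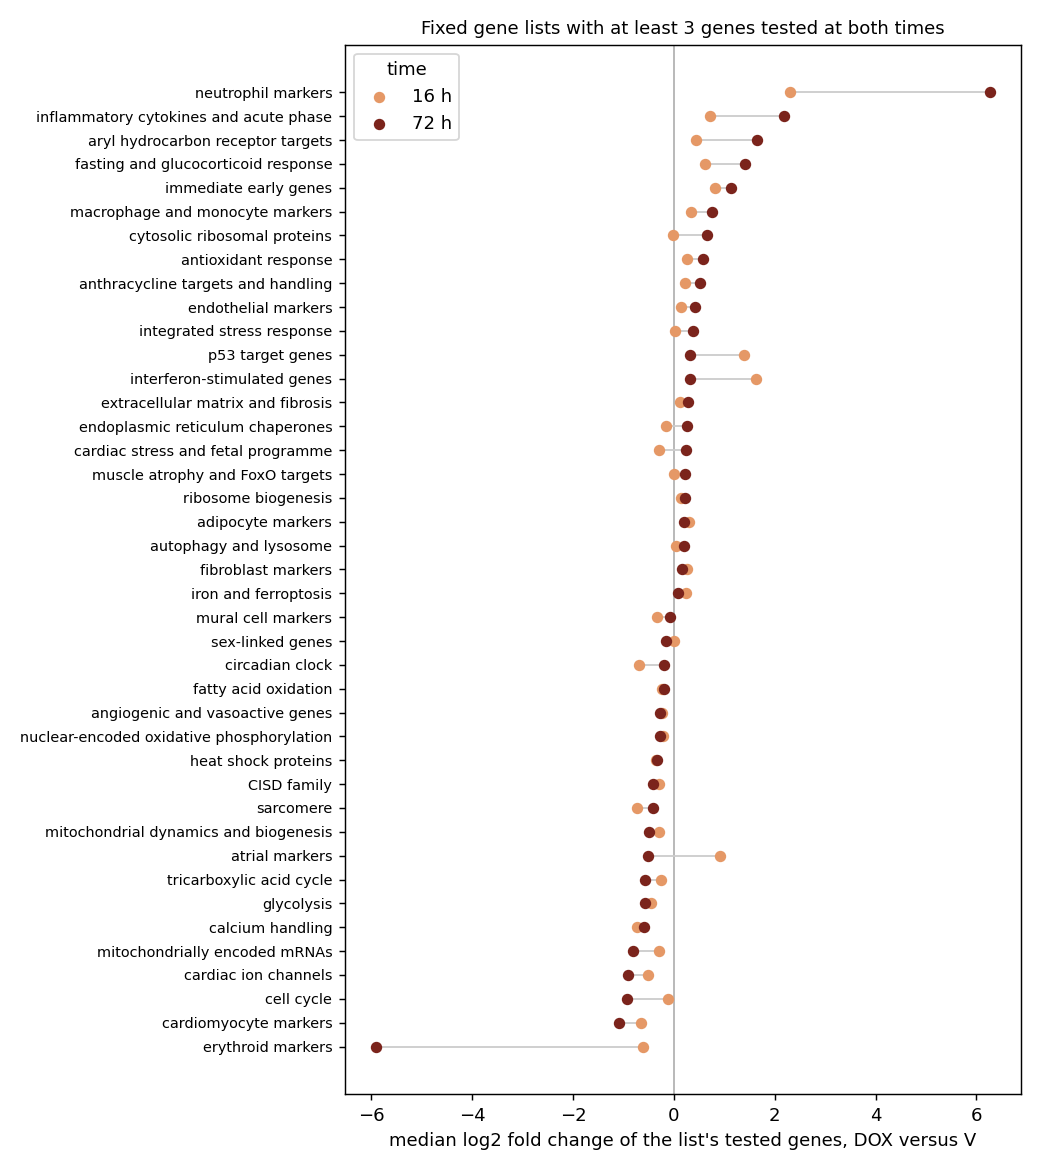
Median log2 fold change of DOX against V for each fixed gene list with at least 3 genes tested at both times, at 16 h (light) and 72 h (dark). The genes tested differ between the times for some lists: interferon-stimulated genes read 1.63 over 24 genes at 16 h and 0.31 over 13 genes at 72 h, and the median difference over the 13 genes tested at both is -1.09. Cytosolic ribosomal proteins move from -0.01 to 0.65 and erythroid markers from -0.61 to -5.92.

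Doxorubicin with hesperitin against doxorubicin alone at 16 h asks whether hesperitin changes the drug's effect. Genes that doxorubicin lowered tended to be higher in DOXH and genes that it raised lower, but no single gene passed the test over all genes. By edgeR 0 of 10393 genes passed (smallest adjusted p = 0.13), with 1958 at an unadjusted p under 0.05. The smallest p belonged to the histone gene H2aw (-0.97 ± 0.16), Asb11 (0.44 ± 0.07), the coenzyme Q gene Coq9 (0.48 ± 0.08) and Tmem117 (1.16 ± 0.20), each at adjusted p = 0.13. Other tools differed: DESeq2 called 390 genes, limma voom 0, and voom with sample quality weights, chosen after seeing the data, 1306.

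The gene lists went the same way but are no stronger evidence, since genes of a list move together and are not replicates. Camera called 21 lists, against as many as 23 when the same libraries were split otherwise, and 0 with an estimated correlation. The share of 18S rRNA also differed, at 0.0751 ± 0.0138% in DOXH and 0.0394 ± 0.00586% in DOX (SD, n = 3). All 77 nuclear oxidative phosphorylation genes had a higher mean in DOXH (median 0.22), and 57 passed adjusted over the list alone, among them Ndufa8 (0.38 ± 0.07) and Cox5a (0.29 ± 0.06). All 22 tricarboxylic acid cycle genes were likewise above DOX, 18 past the threshold adjusted over the list alone, with Idh3a at 0.40 ± 0.09. Of 25 sarcomere genes 21 and of 15 cardiomyocyte markers 14 were higher adjusted over the list alone, for example Myl2 (0.33 ± 0.07), Myoz2 (0.40 ± 0.09) and creatine kinase, Ckm (0.40 ± 0.09). These 4 lists were called (adjusted p = 1.54e-31, adjusted p = 3.53e-13, adjusted p = 2.1e-14 and adjusted p = 3.22e-11), each at adjusted p = 0.221 with an estimated correlation. All 24 interferon-stimulated genes were lower in DOXH adjusted over the list alone (median -0.83, adjusted p = 2.07e-16, adjusted p = 0.326 with an estimated correlation), such as Parp14 (-0.83 ± 0.19) and Rsad2 (-0.64 ± 0.17). Of 27 p53 targets 1 was lower adjusted over the list alone (median -0.47, adjusted p = 7.7e-05, adjusted p = 0.53 with an estimated correlation), and Btg2 read -0.87 ± 0.34 and Plk3 -0.71 ± 0.17. The fibroblast markers had a median of -0.33, with 1 of 19 lower adjusted over the list alone (adjusted p = 0.00397, adjusted p = 0.53 with an estimated correlation). Markers of other cells were also called lower in DOXH: atrial markers (median -0.56, 0 of 9 past the threshold adjusted over the list alone), neutrophil markers (median -0.84, 0 of 9) and macrophage and monocyte markers (median -0.21, 2 of 14), so marker levels of several cell types differ along with the groups. Their adjusted p = 0.0135, adjusted p = 0.0327 and adjusted p = 0.0456 became adjusted p = 0.434, adjusted p = 0.635 and adjusted p = 0.566 with an estimated correlation.

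The 3 DOXH libraries were unlike each other. Along the doxorubicin change of the 3352 called genes, where a library without doxorubicin lies near 0 and the mean of DOX at 1, positions of DOXH and H were measured from the mean of H and those of DOX and V from the mean of V, each library being left out of the means it is measured against. DOXH replicate 1 lay at 0.518, replicate 2 at 0.879 and replicate 3 at 0.0527 (SD 0.414). Measured from V instead they lay at 0.543, 0.904 and 0.0776, which puts replicate 2 within the DOX libraries. The DOX libraries lay between 0.90 and 1.08, V between -0.0211 and 0.0582, and H between -0.0667 and 0.0824 from the mean of H or between -0.0196 and 0.0798 from V. The 3352 genes were called with all DOX and V libraries, so the narrow ranges of DOX and V are in part set by that choice. The slope of the DOXH minus H change on the DOX minus V change, which share no library, was 0.483 (r = 0.828 across genes), 0.276 without DOXH replicate 2 and 0.713 without DOXH replicate 3. Over all 10393 genes it was 0.492, and in simulated data made with a slope of 0.5 the fit gave 0.466. Over the 16 genes called in DOXH against H, the DOX minus V change was regressed on the DOXH minus H change instead. This inverse slope was 0.816 and cannot be read beside the slopes above. A weaker change in DOXH would give an inverse slope above 1, but the set is small and picking it for DOXH minus H draws that slope down. Without DOXH replicate 2, 1554 genes passed in DOXH against DOX, so that 1 library decides whether the count is 0.

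**Figure D4:**
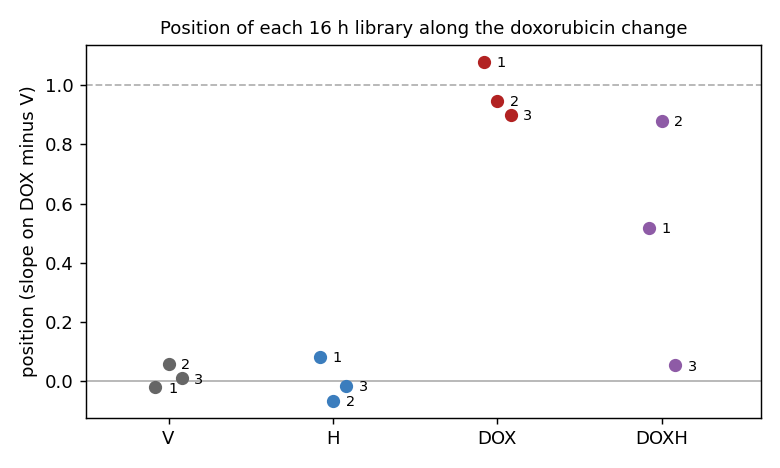
Position of each 16 h library along the doxorubicin change (the slope of its log2 CPM change on DOX minus V over 3352 genes), numbered by replicate. DOXH and H are measured from the mean of H, and DOX and V from the mean of V. The DOXH libraries sit at 0.518, 0.879 and 0.0527, or at 0.543, 0.904 and 0.0776 measured from V.

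Opposite movement was counted directly. Of the genes that rose with doxorubicin, 574 were lower in DOXH than DOX at an unadjusted p under 0.05 (125 if independent), and of those that fell, 995 were higher (192 if independent), while 0 and 1 moved the same way. Both contrasts use the DOX libraries, which alone gives a correlation of -0.49 across genes in 20 simulated draws of unchanged groups, against -0.859 observed. The covariance was -0.148 against -0.021 simulated, a difference of -0.127. The 3 DOX libraries were not split here, since 1 of the parts would hold a single library, so part of the excess over independent lists may come from sharing them.

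Set against vehicle, the DOXH hearts asked what remained of the doxorubicin change. By edgeR 0 genes passed (smallest adjusted p = 0.101), with 1749 at an unadjusted p under 0.05, while DESeq2 called 131, limma voom 0 and voom with sample quality weights 2080. Cldn5 read 2.49 ± 0.38, the clock genes Ciart -1.92 ± 0.28 and Per2 -0.95 ± 0.15, and mt-Co2, the mitochondrial gene of cytochrome oxidase subunit II, -1.13 ± 0.17, each at adjusted p = 0.101. Because mt-Co2 was also lower in H than in V, as given below, its value here does not single out a remnant of the doxorubicin change. Adjusted over the list alone, 20 of 27 p53 targets were higher than in V (median 0.85), with Eda2r at 3.94 ± 0.85, and 14 of 24 interferon-stimulated genes were higher (median 0.70). Of 17 clock genes 9 were lower and 2 higher adjusted over the list alone. The p53, interferon and clock lists were called (adjusted p = 1.32e-08, adjusted p = 2.02e-06 and adjusted p = 0.0024), at adjusted p = 0.504, adjusted p = 0.678 and adjusted p = 0.238 with an estimated correlation. Sarcomere genes had a lower mean than V in 24 of 25 cases (5 lower adjusted over the list alone, median -0.29) and cardiomyocyte markers in 15 of 15 (1 adjusted over the list alone, median -0.28). Calcium handling (4 of 23 lower adjusted over the list alone, median -0.26) and glycolysis (2 of 22, median -0.20) went the same way. These 4 lists were called lower (adjusted p = 1.32e-08, adjusted p = 3.94e-06, adjusted p = 6.75e-06 and adjusted p = 4.02e-05), each at adjusted p = 0.504 with an estimated correlation. Neutrophil markers were called higher (9 of 9 above V, 0 adjusted over the list alone, median 1.53) and mural cell markers lower (12 of 13 below V, 0 adjusted over the list alone, median -0.28), at adjusted p = 0.0024 and adjusted p = 0.00281, and adjusted p = 0.678 and adjusted p = 0.504 with an estimated correlation. Oxidative phosphorylation genes differed by a median of 0.00, with 0 of 77 past the threshold adjusted over the list alone. Without DOXH replicate 3 the count of changed genes was 1674.

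Against hesperitin alone, which isolates doxorubicin on a hesperitin background, 12 genes rose and 4 fell. Cldn5 rose by 3.01 ± 0.38 (adjusted p = 0.0221), the transcription factor gene Fosl2 by 2.21 ± 0.35, the kinase gene Sik1 by 1.92 ± 0.31 and Arntl by 1.59 ± 0.26. Ciart (-1.72 ± 0.28), the stress factor gene Ddit3 (-0.94 ± 0.15) and Cd200, which encodes a surface protein that restrains myeloid cells (-1.36 ± 0.16), fell. The synaptic scaffold gene Shank3 rose by 0.57 ± 0.07 (adjusted p = 0.0175), and its level set H apart: 50.1 ± 1.79 CPM in H, 72.4 ± 2.89 in V, 69.1 ± 3.92 in DOX and 74.5 ± 1.44 in DOXH (SD, n = 3). Among p53 targets 20 of 27 were higher adjusted over the list alone (median 0.89, camera adjusted p = 1.36e-06, adjusted p = 0.492 with an estimated correlation). Markers of several cell types moved along: neutrophil (median 1.07), macrophage and monocyte (0.30, 5 of 14 higher adjusted over the list alone) and endothelial markers (0.24, 8 of 21 higher and 1 lower) were called higher, and cardiomyocyte (-0.29, 6 of 15 lower) and mural cell markers (-0.31, 1 of 13 lower) lower. Their adjusted p = 0.000119, adjusted p = 0.00288, adjusted p = 0.0316, adjusted p = 9.96e-06 and adjusted p = 0.0177 became adjusted p = 0.536, adjusted p = 0.492, adjusted p = 0.492, adjusted p = 0.492 and adjusted p = 0.536 with an estimated correlation. The 16 calls are fragile: 0 genes passed without H replicate 3, without V replicate 1, with only these groups in the fit or against a fold of 1.5, and 2298 passed without DOXH replicate 3. DESeq2 called 718, and the H libraries hold 17664060 to 19869050 counts against 9255651 to 10502391 in DOXH.

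Hesperitin alone against vehicle at 16 h shows the compound in hearts without the drug. No gene passed: edgeR called 0 (smallest adjusted p = 0.073, Shank3 at -0.53 ± 0.07), with 664 at an unadjusted p under 0.05, DESeq2 called 13, limma voom 0 and voom with sample quality weights 16. Other small p-values belonged to mt-Co2 (-1.07 ± 0.17), the methyl-CpG-binding gene Mbd1 (-1.02 ± 0.17) and Zfhx2 (-0.72 ± 0.12). Camera called endothelial markers lower (median -0.26, with 1 of 21 lower adjusted over the list alone, Eng at -0.44 ± 0.09; adjusted p = 0.00152, adjusted p = 0.172 with an estimated correlation). Heat shock genes were also called, with 4 of 17 lower adjusted over the list alone, such as Hspa1b at -1.27 ± 0.30 (adjusted p = 0.00152, adjusted p = 0.896 with an estimated correlation). The fasting and glucocorticoid list had a median of -0.34 and 0 of 20 past the threshold adjusted over the list alone (adjusted p = 0.00162, adjusted p = 0.896 with an estimated correlation). Oxidative phosphorylation genes were called higher (52 of 77 above V, 0 adjusted over the list alone, median 0.04). Mitochondrially encoded mRNAs (3 of 13 lower adjusted over the list alone) and immediate early genes (1 of 18) were called lower. The camera adjusted p = 0.0132, adjusted p = 0.0398 and adjusted p = 0.0132 became adjusted p = 0.976, adjusted p = 0.896 and adjusted p = 0.896 with an estimated correlation. The H libraries were 1.77 times as deep as the mean of the other 9, and the H minus V change fell with GC content across genes (Spearman -0.365 over 10385 genes), against -0.094 for DOX minus V. Without H replicate 1 the count was 47 genes.

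The interaction asks whether hesperitin acts differently with and without doxorubicin. By edgeR 0 genes passed (smallest adjusted p = 0.172), with 1228 at an unadjusted p under 0.05, DESeq2 called 53, limma voom 0 and voom with sample quality weights 226. Mitochondrially encoded mt-Nd3 had an interaction of 1.12 ± 0.16 and mt-Co3 one of 1.03 ± 0.18 on the log2 scale: mt-Nd3 read 6103 ± 324 CPM in V, 3961 ± 685 in H, 4609 ± 378 in DOX and 6518 ± 466 in DOXH (SD, n = 3). All 24 interferon-stimulated genes had a negative interaction (median -0.88), with 0 past the threshold adjusted over the list alone, and 72 of 77 oxidative phosphorylation genes a positive one (median 0.18), with 5 past it. All 15 cardiomyocyte markers were positive too (median 0.43, 0 past it). The 3 lists were called (adjusted p = 9.16e-13, adjusted p = 1.14e-14 and adjusted p = 5.42e-07), each at adjusted p = 0.328 with an estimated correlation. Because this contrast includes H minus V, the depth and GC trend of the H libraries enter it (Spearman 0.221 with GC content). Without DOXH replicate 2 the count was 254 genes, and without H replicate 1 it was 29.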

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

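All tests of explanations for the loss of erythroid transcripts were chosen after the result was seen, and the counts over other splits were planned. The results below stand here because the doxorubicin change differed between 72 h and 16 h in a test of the difference itself, which 1960 genes passed.

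The doxorubicin change of several stress genes was higher at 72 h than at 16 h: Nppb by 7.41 and Myh7 by 5.99 on the log2 scale, Ankrd1 by 4.09, the cytokine receptor gene Tnfrsf12a by 3.54, the calcineurin regulator Rcan1 by 2.18 and the antioxidant enzyme gene Nqo1 by 1.04. Nppb had been among the largest falls at 16 h, so much of its difference is the loss of that fall and not a rise above V. Hspb7, a small heat shock protein gene of heart muscle (1.63), and the clock gene Per2 (1.09) had also fallen at 16 h and differed upward. The p53 targets Ccng1 (-1.76) and Mdm2 (-1.65) and the interferon-stimulated genes Parp14 (-1.44) and Gbp3 (-2.14) went the other way, as did Cldn5 (-1.96). Citrate synthase Cs (-0.86), the complex III gene Uqcrc1 (-0.65) and mt-Nd2 (-0.78) fell further, while Rpl3 (1.22) and Rpl10a (0.91) were higher.

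By list, the median difference was 0.64 for cytosolic ribosomal proteins, 0.72 for cardiac stress genes (7 of 15 higher), 0.49 for chaperones of the endoplasmic reticulum (4 of 19 higher and 1 lower) and 0.39 for endothelial markers (7 of 21 higher and 1 lower). It was -1.09 for interferon-stimulated genes, -0.63 for p53 targets (7 of 19 lower and 1 higher), -0.36 for the tricarboxylic acid cycle (14 of 22 lower and 2 higher), -0.54 for mitochondrially encoded mRNAs (10 of 13 lower) and -0.086 for oxidative phosphorylation (16 of 77 lower and 4 higher). For the mitochondrially encoded mRNAs, mt-Nd2 included, nuclear copies of mitochondrial sequence held counts at 72 h alone, which may enter the difference. With an estimated correlation none of these lists was called, and with a block for the replicate number 1214 genes and 5 lists were. Of 100 splits drawn, 3 gave at least 1960 genes, the real split included, and the highest other gave 2191. The 2 others as large kept the real groups of 72 h and mixed those of 16 h. Most splits mix DOX with V within a time and so remove the doxorubicin effect itself, so this share does not test whether the effect differs between the times. For the list count chance cannot be excluded: 62 of the 100 splits gave at least 10 lists, and the highest other gave 26.

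Erythroid transcripts were the strongest loss among the lists, with a median difference of -5.27 (Hbb-bt -7.48, Hbb-bs -5.89 and Alas2 -5.78). Reads shared between paired globin genes cannot produce it, because the summed CPM of the 4 globin genes fell from 2384 ± 1040 in V to 27.1 ± 6.23 in DOX at 72 h, a log2 ratio of -6.46, against -0.642 at 16 h. Less blood in the hearts may contribute, but neutrophil markers, also carried by blood, rose by a median of 6.27, and blood volume and inflow of neutrophils cannot be told apart here. Fewer young red cells in the circulation are a candidate explanation, since all 4 globin genes and Alas2 differed by -5.27 or more, but no blood count was analysed here.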

How the results depend on the processing

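Alternatives that change a result are given here, and those chosen after seeing the data are voom with sample quality weights, offsets corrected for GC content and leaving out libraries of groups not compared. The planned comparisons of hesperitin at 72 h were not run, because 6 columns matched no label. Leaving low counts unfiltered removes no gene at 16 h or between the times and so gives no value there. With a correlation estimated per list, 0 lists were called in each of the 8 comparisons.

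Doxorubicin against vehicle at 16 h changed 3352 genes, 91 against a fold of 1.5 and 5122 by voom with sample quality weights. With 1 library left out the count ran from 1928 (without V replicate 1) to 4031 (without DOXH replicate 2). Cisd2 was no longer past the threshold with a replicate block (-0.2636) or against a fold of 1.5 (-0.2631), and ran from -0.3378 to -0.219 with 1 library left out. At 72 h the count was 826 against a fold of 1.5, where Cisd2 (-0.4072) also missed the threshold.

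Against doxorubicin alone, DOXH changed 0 genes by edgeR (1958 at an unadjusted p under 0.05) and 0 by limma voom, but 390 by DESeq2, 1306 by voom with sample quality weights, 1 with only the groups compared and 0 to 1554 with 1 library left out (most without DOXH replicate 2). Hesperitin alone changed 0 genes by edgeR (664 at an unadjusted p under 0.05) and 0 by limma voom, 13 by DESeq2, 16 by voom with sample quality weights and 0 to 47 with 1 library left out (most without H replicate 1), and its lists ran from 5 to 15. Against vehicle, DOXH changed 0 genes by edgeR (1749 at an unadjusted p under 0.05) and 0 by limma voom, 131 by DESeq2, 2080 with quality weights, 1 with only the groups compared and 0 to 1674 with 1 library left out (most without DOXH replicate 3).

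Against hesperitin alone, DOXH changed 16 genes by edgeR, 55 with upper quartile factors, 718 by DESeq2, 29 by limma voom, 2113 with quality weights and 7 with a replicate block. With only the groups compared or against a fold of 1.5 the edgeR count was 0 (2558 at an unadjusted p under 0.05 in the fit of all groups). It ran from 0 (without H replicate 3 or V replicate 1) to 2298 (without DOXH replicate 3). The interaction went from 0 (1228 at an unadjusted p under 0.05, 0 by limma voom) to 53 by DESeq2, 226 with quality weights and 254 without DOXH replicate 2. The time difference went from 1960 to 108 against a fold of 1.5, 3044 with quality weights and 1214 with a replicate block (1163 shared), where its lists went from 10 to 5.

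At 16 h replicate numbers do not pair the libraries: 0 of 12 were closest to one with their own number. At 72 h 4 of 5 were, with correlations of 0.197 and 0.245 in the 2 same-number pairs, too few to settle whether numbers pair there, so the blocked counts of the time difference stand as an open alternative. Of 4438 alternative values of the 216 gene values tested, 4064 kept their side of the threshold, 234 lost it and 140 gained it. Where the main or the alternative value was past the threshold, 0 changed direction. Changes of direction between values that were not past it were not counted. With offsets corrected for GC content, 3318 genes changed with doxorubicin at 16 h (3129 shared) and 0 with hesperitin alone (471 at an unadjusted p under 0.05).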

Other observations

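Tests of the spread of the DOXH libraries, of depth and of a shared hesperitin effect were chosen after the result was seen, while the GC test and the counts over other splits were planned. At 72 h doxorubicin also raised many genes of antioxidant defence and detoxification. Of 26 antioxidant genes 14 rose and 3 fell (median 0.58, camera adjusted p = 0.00543, adjusted p = 0.452 with an estimated correlation), among them the quinone reductase gene Nqo1 (1.22 ± 0.11) and the glutathione transferase genes Gsta1 (2.75 ± 0.34) and Gstm1 (1.22 ± 0.10). All 4 tested targets of the aryl hydrocarbon receptor rose (median 1.65, adjusted p = 0.0215, adjusted p = 0.452 with an estimated correlation), such as Cyp1b1 (2.07 ± 0.34). The ferritin heavy chain Fth1 rose by 1.24 ± 0.10. At 16 h the transferrin receptor gene Tfrc changed by -2.48 ± 0.42 and the iron exporter gene Slc40a1 rose by 2.14 ± 0.38, while the iron list as a whole went both ways (5 of 19 up, 4 down).

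Matrix genes changed unevenly at 72 h: 10 of 29 rose and 3 fell, and the list was not called (adjusted p = 0.11). The collagen cross-linking enzyme Lox (2.63 ± 0.33), the membrane protease gene Mmp14 (2.30 ± 0.13) and the matricellular gene Ccn2 (2.62 ± 0.18) rose. Of 23 genes of autophagy and lysosomes 11 rose and 4 fell, with the mitophagy receptor Bnip3 at 1.59 ± 0.13, and the fusion gene Opa1 changed by -1.34 ± 0.10.

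The first pattern weighed is the spread of the 3 DOXH libraries, at 0.518, 0.879 and 0.0527 along the doxorubicin change from the mean of H, or 0.543, 0.904 and 0.0776 from V, where replicate 2 lies within the DOX libraries. A wrong label was asked over 4 gene sets, chosen after the spread was seen: over the mitochondrially encoded mRNAs DOXH replicate 2 lay 0.408 from DOX against 0.221 from its own group, and replicate 3 lay 0.331 from V against 0.093, while replicate 3 lay within the range of the H libraries over all 4 sets, after which the rule for reading these distances was made stricter. Over all 10393 genes replicate 2 lay nearer DOX, and replicate 3 nearer V or H, than their own group, as their positions already show, and the other 2 sets support no wrong label, because 0 of the V, DOX and DOXH libraries over genes at an unadjusted p over 0.5, and 6 of 12 libraries over ribosomal proteins, lay nearest their own group. Against an H library, replicate 3 held 10116855 counts with 1.22% mitochondrial rRNA (H 17664060 to 19869050 and 0.745% to 0.972%), and against a DOX library, replicate 2 held 0.0874% 18S rRNA (DOX 0.0327% to 0.0437%), but these are single libraries and V stays open for replicate 3. Replicate 2 minus replicate 3 followed DOX minus V across genes (r = 0.791), which unequal exposure, unequal response to hesperitin or a wrong label could each give, and with 3 libraries and no measured exposure these cannot be told apart.

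The second pattern is the difference between H and V. Its trend with GC content (Spearman -0.365) is what a bias of preparation or sequencing would give, and the H libraries were 1.77 times as deep as the other 9, so depth or preparation shared by the group cannot be told apart from hesperitin. If hesperitin acted on the same genes with and without doxorubicin, H minus V should follow DOXH minus DOX. Over 390 genes at an unadjusted p under 0.05 in H against V and not in DOX against V, the correlation was 0.048. It was -0.235 over all 664 genes at that p in H against V. Over 1902 genes at an unadjusted p over 0.5 in DOX against V it was 0.157. No gene passed the adjusted test in H against V, and the first spread also enters DOXH, so these values decide nothing.

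Other splits of the libraries were counted for each result. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real and highest other counts of genes were 3352 and 0 for DOX against V at 16 h, 4133 and 0 at 72 h, 0 and 68 for DOXH against DOX (edgeR; 1958 at an unadjusted p under 0.05), 0 and 0 for H against V (664), 0 and 1 for DOXH against V (1749) and 16 and 259 for DOXH against H. For lists they were 21 and 28, 21 and 20, 21 and 23, 6 and 18, 16 and 18, and 17 and 22 in the same order. The split with 259 genes set DOXH replicates 1 and 2 with H replicate 1 against DOXH replicate 3 with H replicates 2 and 3. The first side held the higher positions along the doxorubicin change (0.518, 0.879 and 0.0824, against 0.0527, -0.0667 and -0.0157, from the mean of H). This split therefore goes along with the spread of the DOXH libraries, and any further structure was not tested. For the interaction the real gene count is 0 (edgeR; 1228 at an unadjusted p under 0.05; 53 by DESeq2, 0 by limma voom), so each of 100 splits drawn is at least as large by construction and the count tests nothing (highest other 3). For its lists chance cannot be excluded: 44 of 100 gave at least 15 (highest other 28).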
